A study of Homo sapiens with 4 samples.

How the data were processed

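The study compared HaCaT cells given recombinant human LRG1 in PBS with cells given PBS, with 2 libraries in each of the 2 groups, taken from the labels. RNA was extracted with Trizol and libraries were prepared with a TruSeq RNA kit, per the labels' protocols. Reads were processed with cutadapt, HISAT2 2.0.4 and StringTie 1.2.3 against the hg19 genome, per the submitters' processing notes, which give no settings for these tools. The deposited table gives FPKM per gene and library, per the file headers, for 11533 genes, each listed as protein-coding. The highest value of any listed gene was at least 0.517 FPKM, so genes low in all libraries are absent from it by a filter not given in the sources used here. Gene symbols, identifiers and hg19 positions are those of the table. An FPKM value is relative to the mapped fragments of its own library, so an equal shift of all transcripts cannot be seen.

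Columns were matched to libraries by name. The control columns begin with con and end in the replicate number. The columns used for LRG1 are spelled Lvgl, followed by the replicate number; they were taken as the LRG1 libraries because they are the only columns not named as controls and begin with the same letter. This reading of the name cannot be checked against the values, since protein added to the medium adds no LRG1 transcript, and every direction given rests on it. All 4 columns were mapped.

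The values are not counts, so depth per library is unknown, and the test planned for normalised values was used. A search for whole multiples of 1 read began from 213 single-exon genes, with lengths from GENCODE release 29 and a tolerance of 0.1 reads. The share of whole values was taken over low values only, 20 to 36 per library. At best 56.0% of 25 values were whole, in LRG1 library 1, and up to 52.4% after random rescaling, so no read numbers were recovered. Some values are exactly 0 (25 and 9 in control libraries 1 and 2, 19 and 10 in LRG1 libraries 1 and 2); such a 0 may be a failed estimate, and these genes are described as listed at 0.

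Genes with at least 1 FPKM in at least 2 libraries were tested (10633). A linear model with group as its only term was fitted to log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and a mean-variance trend, and Benjamini-Hochberg adjustment over all genes tested at a threshold of 0.05, two-sided. Fold changes are on the log2(FPKM + 1) scale and understate the change of low genes. The residual degrees of freedom were 2 and the prior degrees of freedom 2.10. The spread of each gene thus rested on its own very few values and, about equally, on the trend fitted over all genes tested.

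The design, the test, the alternatives, the rule for named genes and 35 gene lists were fixed before the data were examined. Lists with at least 5 genes tested (30 of them) were compared with the other genes by camera in limma at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists; camera with an estimated correlation and fry were run beside it. By the rule, the genes named were up to 12 with the largest change in each direction among those past the threshold, with non-overlapping groups and a mean of at least 1 FPKM; LRG1, TGF-beta family receptors and SMADs; and for each list up to 4 members past the threshold or otherwise up to 2 with the smallest p. The table repeats 5 gene symbols over 10 entries, which were left out of the first part of the rule. Some genes that the rule selects are not reported here.

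The test was first run on simulated data made from these genes with 200 of 10633 changed. In 20 simulations it recovered 24.9% of genes changed 1.5-fold, 52.8% of those changed 2-fold and 81.2% of those changed 4-fold, with 4.45 false calls on average, and with no gene changed it made 0 calls. A random list reached p under 0.05 by camera in 1 of 20 simulations. The simulated noise was normal and independent for each gene, so it held no switches of level and no correlation between genes. False calls from either could therefore not appear.

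Alternatives were another pseudocount (0.1), no filter and a stricter filter (mean of at least 5 FPKM), a common total, quantile normalisation, median-of-ratios scaling, moderation without the trend, the replicate number as a block, and leaving out each library. Added after the data were seen was a test without genes that overlap another protein-coding gene on the same strand, judged by gene ID in GENCODE release 29 (11474 of 11533 IDs, 99.49%, matched). Coordinates of that release were used for overlap only and are not printed. Overlap was judged from whole gene spans, introns included, so it need not mean that exons or reads are shared. Overlap with noncoding genes or with genes on the other strand was not tested. Intervals of the estimated correlations, also added after the data were seen, took the variance inflation of a list as chi-squared with the residual degrees of freedom. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.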

Results

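Gene expression was measured by RNA sequencing in HaCaT cells, an immortal human keratinocyte line, with or without recombinant human LRG1. LRG1 (leucine-rich alpha-2-glycoprotein 1) is a secreted glycoprotein known to modulate TGF-beta family signalling. The LRG1 group held 2 libraries from cells given the protein at 500 ng/ml for 12 h, and the control group held 2 libraries from cells given the same volume of PBS. All 4 libraries came from cells at passage 8. The table analysed here lists 11533 protein-coding genes in FPKM, a read abundance scaled by transcript length and by the mapped fragments of the library. FPKM values summed to 206168 and 204947 in control libraries 1 and 2 and to 205229 and 204501 in LRG1 libraries 1 and 2, with medians between 6.13 and 6.15. These sums do not show sequencing depth, which is unknown, so no counting error or detection limit can be given for any gene.

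The cells carried the transcripts of cultured keratinocytes. KRT14, a keratin of basal keratinocytes, was at 607 ± 11.7 FPKM and its partner KRT5 at 259 ± 12.5 FPKM (mean ± SD, n = 4 libraries). KRT19 was at 328 ± 8.61 FPKM, KRT6A at 291 ± 4.41 FPKM and the proliferation marker MKI67 at 84.3 ± 1.38 FPKM. The differentiation keratins were lower, with KRT10 at 19.9 ± 0.464 FPKM and KRT1 at 1.25 ± 0.262 FPKM. The 13 mitochondrially encoded genes took between 16.3% and 16.7% of the summed FPKM. Across the 10633 genes tested, the SD of the log2 difference between libraries was 0.265 for the pair of controls, 0.274 for the pair of LRG1 libraries and 0.270 to 0.274 for the pairs taken across the groups. The pairs across the groups thus lay above the pair of controls and no higher than the pair of LRG1 libraries.

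The comparison of LRG1 with control asks which transcripts of these keratinocytes differ after 12 h with the added protein. In the LRG1 libraries 12 genes were higher and 12 were lower at an adjusted p under 0.05 (limma, Benjamini-Hochberg, 10633 genes). On the log2(FPKM + 1) scale the largest fall was in HSPA2, a member of the HSP70 chaperone family (ENSG00000126803, chromosome 14, 65002623 to 65012891, hg19), from 14.5 ± 0.472 FPKM in controls to 1.34 ± 0.0422 FPKM with LRG1 (mean ± SD, n = 2 each). The largest rise on that scale was in ZDHHC20, a palmitoyltransferase (ENSG00000180776, chromosome 13, 21946712 to 22033509, hg19), from 6.44 ± 0.243 to 28.4 ± 2.42 FPKM. Their log2 fold changes were -2.73 (SE 0.07, limma adjusted p = 0.0169) for HSPA2 and 1.98 (SE 0.08, limma adjusted p = 0.0337) for ZDHHC20. In each of the 24 genes both LRG1 values lay on the same side of both control values.

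Among the genes that fell were 2 ubiquitin-pathway ligases. TRIM32, a RING-type E3 ubiquitin ligase (chromosome 9, 119449581 to 119463579, hg19), fell from 12.3 to 2.16 FPKM (log2 fold change -2.08, SE 0.07, limma adjusted p = 0.0295). RNF4, a ligase that targets SUMO-modified proteins (chromosome 4, 2463947 to 2627047, hg19), fell from 8.32 to 2.26 FPKM. MXD1, a partner of MAX that antagonises MYC, fell from 6.07 to 0.882 FPKM, and GINS4, a subunit of the GINS replication complex, from 11.9 to 3.65 FPKM. The signalling adaptors FRS2 and CRK fell from 5.09 to 1.71 FPKM and from 38.3 to 22.6 FPKM. PRDX2, a cytosolic peroxiredoxin, had the smallest fall on the log2 scale, from 78.8 to 50.4 FPKM (log2 fold change -0.63). RTL10 went from 9.65 to 2.26 FPKM, GUCD1 from 7.09 to 2.90 FPKM, HNRNPA1L2 from 8.39 to 2.45 FPKM and SULT1A4 from 5.50 to 1.72 FPKM. HNRNPA1L2 and SULT1A4 have near-identical relatives elsewhere in the genome, so their values are uncertain.

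Among the genes that rose, GRB2, the adaptor that links receptor tyrosine kinases to RAS (chromosome 17, 73314157 to 73401790, hg19), went from 5.39 to 17.9 FPKM (log2 fold change 1.57, SE 0.10, limma adjusted p = 0.0427). ELK3, an ETS-family transcription factor (chromosome 12, 96588160 to 96663613, hg19), rose from 5.28 to 15.1 FPKM, with a log2 fold change of 1.37 (SE 0.09, limma adjusted p = 0.0465). PTP4A1, a prenylated phosphatase, rose from 9.33 to 20.4 FPKM, and NABP2, a single-stranded DNA binding protein, from 9.61 to 22.6 FPKM. SURF4, a cargo receptor of the early secretory pathway, had the smallest rise on the log2 scale, from 38.9 to 67.5 FPKM (log2 fold change 0.78). TMEM9B rose from 6.27 to 16.0 FPKM, PLEKHB2 from 9.62 to 23.4 FPKM and RNASEK from 9.87 to 21.4 FPKM. AC005324.3 rose from 1.40 to 6.97 FPKM. AL713999.1 was listed at 0 in both controls and at 2.21 and 2.71 FPKM with LRG1. AC245033.1, named here after its values were seen because its mean lay below 1 FPKM, was at 0.0859 and 0.0883 FPKM in controls and at 1.68 and 2.02 FPKM with LRG1.

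**Figure D1:**
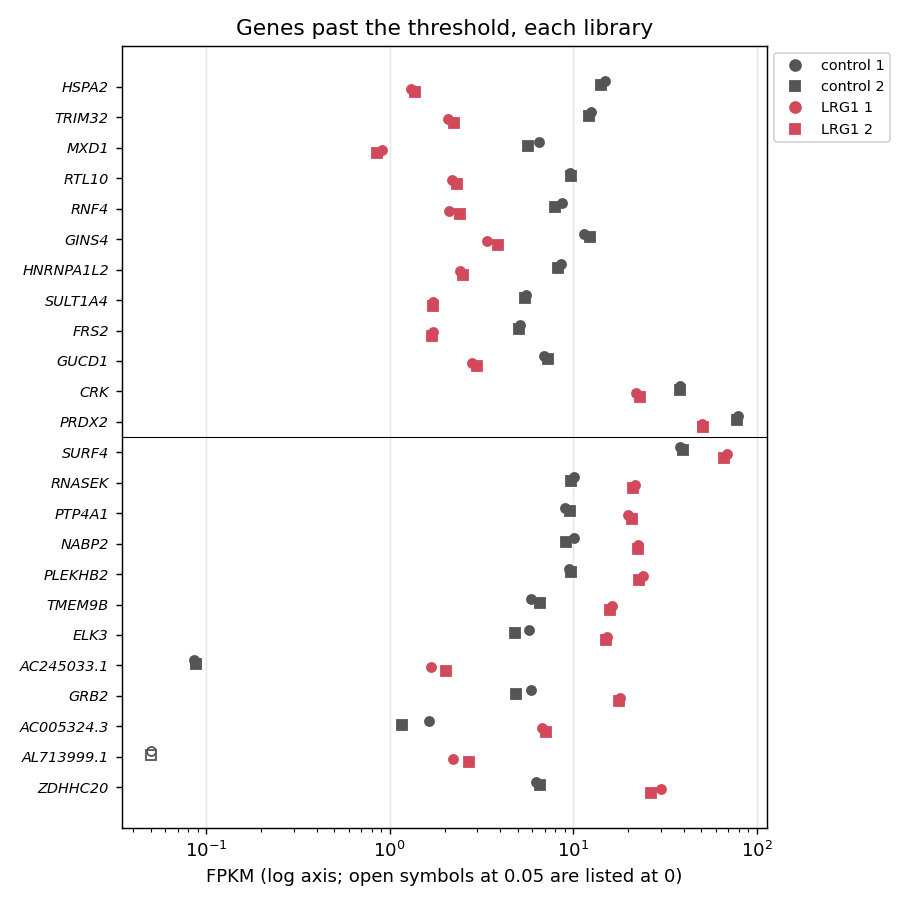
FPKM (log axis) of the 24 genes past the threshold, 1 point per library, with circles for replicate 1, squares for replicate 2, controls in grey and LRG1 in red. The genes above the line were lower with LRG1, led by HSPA2 (14.5 to 1.34 FPKM), those below it were higher, and open symbols stand for AL713999.1, listed at 0 in both controls.

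Of the 24 genes, 21 changed by at least 2-fold on the log2(FPKM + 1) scale, 11 upward and 10 downward. At an unadjusted p under 0.05 limma found 522 genes, 262 higher and 260 lower. Chance alone would give a share of 0.05 of the 10633 genes tested, and 522 is no more than that. The LRG1 and control values did not overlap in 1911 genes that were higher and 1932 that were lower, together 36.1% of the genes tested, where chance gives 33.3% for 2 libraries against 2. Nothing in the labels says that the libraries came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. In simulated data with the same design the test recovered 52.8% of genes changed 2-fold and 81.2% of those changed 4-fold. The noise there was normal and independent for each gene, so it held no switches of level.

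With any 1 library left out, none of the 24 genes that could still be tested (22 or 23) passed the threshold (limma, Benjamini-Hochberg), with 1 residual degree of freedom. Each kept its sign and between 91.9% and 108% of its log2 fold change. Passing the threshold had required close replicates in these same libraries, so such stability was largely fixed in advance and is no support for the calls. The calls were lost whichever library was left out, so their loss does not point to any of the libraries. Without control library 1 limma called 0 genes, with 571 at an unadjusted p under 0.05, and without control library 2 it called 0, with 540. Without LRG1 library 1 it called only AP002990.1 (590 genes at an unadjusted p under 0.05) and without LRG1 library 2 only AHNAK (706 genes), 2 genes named after their values were seen, each with 1 library far from the others. AHNAK was at 153, 151 and 155 FPKM in 3 libraries and at 5.73 FPKM in LRG1 library 1, and 90 genes tested had 1 library over 1 log2 unit away from 3 closely matched ones. Of the called genes, 10 (41.7%) overlap another protein-coding gene on the same strand, among them MXD1, RNF4, RTL10, PRDX2, PTP4A1, PLEKHB2, RNASEK, AC005324.3, AC245033.1 and AL713999.1, so these values are uncertain.

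Transcripts of the interferon response passed as a group, lower with LRG1, in the camera test at a preset inter-gene correlation of 0.01 (limma, Benjamini-Hochberg over 30 lists, adjusted p = 0.00315). The call did not hold with an estimated correlation (camera in limma, p = 0.0649, adjusted p = 0.699) or without LRG1 library 1 (adjusted p = 0.527, median log2 fold change -0.09). The estimate, 0.00933, was below the preset correlation, but that form of the test also uses the 2 residual degrees of freedom. Of 23 genes tested, 16 had a negative log2 fold change, 12 had both LRG1 values below both controls and 1 had both above. The median log2 fold change was -0.13 with all libraries. ISG15, a ubiquitin-like protein induced by interferon, was at 32.9 and 34.2 FPKM in controls and 28.2 and 26.9 FPKM with LRG1 (log2 fold change -0.27, limma adjusted p = 0.535), and IFIT1, an RNA-binding interferon-induced protein, was at 21.7 and 22.0 against 18.1 and 18.9 FPKM (log2 fold change -0.23, limma adjusted p = 0.694).

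Immediate early genes of the EGFR, MAPK and AP-1 pathways also passed as a group at the preset correlation, lower with LRG1 (limma camera, Benjamini-Hochberg, adjusted p = 0.00315). The call did not hold with an estimated correlation of 0.175 (camera in limma, p = 0.228, adjusted p = 0.699), without LRG1 library 1 (adjusted p = 0.527, median -0.03) or under the stricter filter (adjusted p = 0.109). With all libraries 26 of 30 genes tested had a negative log2 fold change and the median was -0.07, and without LRG1 library 2 it was -0.15. In 10 of the genes both LRG1 values lay below both controls, and in 0 both lay above. JUN, a component of AP-1, was at 13.9 and 14.6 FPKM in controls and 11.2 and 12.0 FPKM with LRG1 (log2 fold change -0.28, limma adjusted p = 0.760), and SPRY2, a feedback inhibitor of MAPK signalling, was at 1.99 and 2.12 against 1.48 and 1.48 FPKM (log2 fold change -0.30, limma adjusted p = 0.813). In both lists 0 genes passed over all genes tested and 0 when adjusted over the list alone, and limma's fry test, which asks whether a list moves 1 way, called 0 of the 30 lists. Of the 30 lists, 0 passed camera with an estimated correlation. With 1 library left out the median of 29 of them moved by over 1.5 times or changed sign, and in 10 it changed sign, so small medians are uncertain; the interferon list was the exception.

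**Figure D2:**
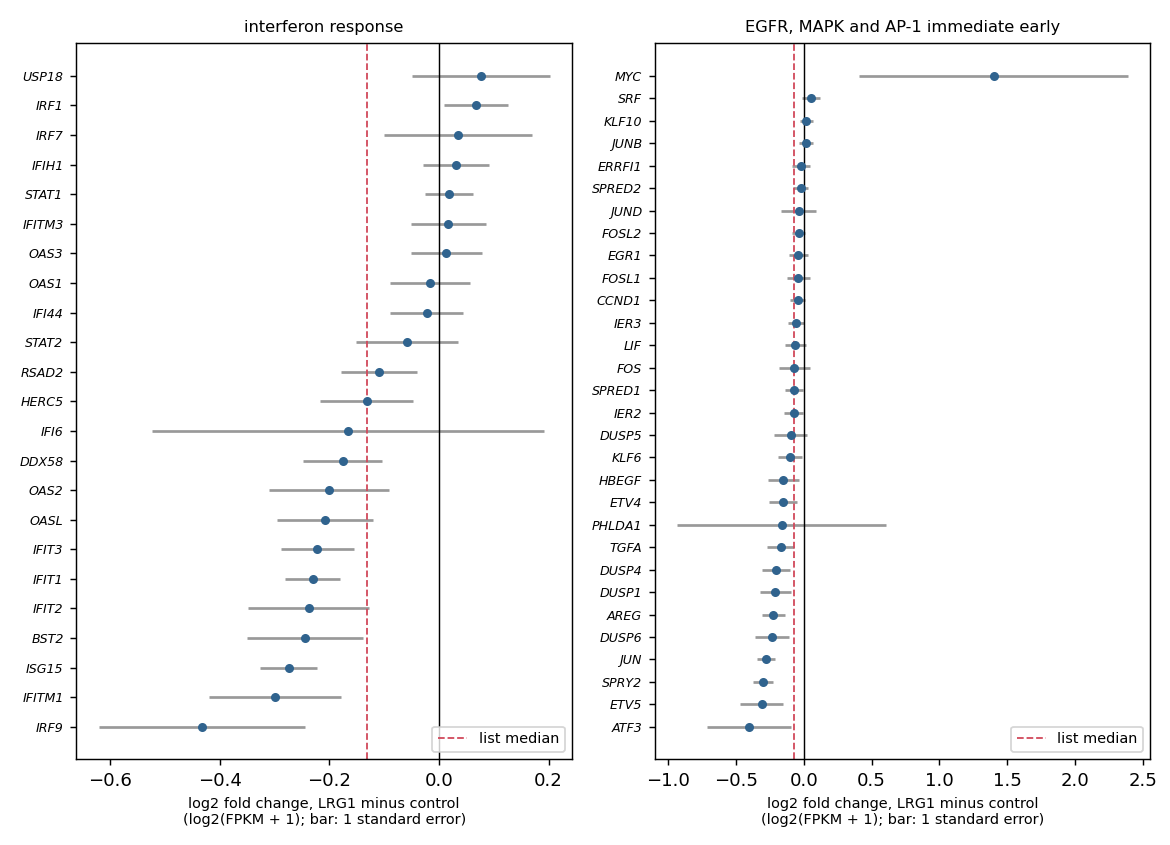
Log2 fold change (LRG1 minus control, on log2(FPKM + 1)) of each tested member of the interferon response list and of the EGFR, MAPK and AP-1 immediate early list; points are estimates, bars 1 standard error, and the dashed red line is the list median. The medians lie at -0.13 and -0.07, and 16 of 23 and 26 of 30 members lie below 0.

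Of 21 TGF-beta SMAD2/3 targets tested, 15 had a negative and 6 a positive log2 fold change, with a median of -0.07 (camera in limma, adjusted p = 0.138; 0 members passed over all genes and 0 adjusted over the list alone). The list passed camera in limma without a filter (adjusted p = 0.0427), without LRG1 library 2 (adjusted p = 0.0399) and without control library 2 (adjusted p = 0.0375), and had a median of -0.04 without LRG1 library 1 (adjusted p = 0.527). ITGB6, an integrin subunit that activates TGF-beta, was at 17.6 and 16.7 FPKM in controls and 19.8 and 19.6 FPKM with LRG1, and TAGLN was at 2.83 and 3.07 against 2.04 and 2.40 FPKM. The LRG1 transcript itself was low, at 1.72 and 1.64 FPKM in controls and 1.47 and 1.73 FPKM with LRG1 (log2 fold change -0.05). The type II receptor TGFBR2 was at 20.4 and 19.1 against 17.8 and 17.7 FPKM (log2 fold change -0.15, limma adjusted p = 0.879). TGFBR1 was near 10 FPKM in 3 libraries, at 10.2, 10.4 and 10.1 FPKM, and at 3.87 FPKM in LRG1 library 2. ACVR2A had a log2 fold change of -0.41, SMAD3 of 0.09 and SMAD4 of 0.08, and none of the 15 receptors, SMADs and LRG1 tested passed (camera in limma, adjusted p = 0.784 for the list; 0 genes adjusted over the list alone). The 12 BMP SMAD1/5 targets had 6 positive and 6 negative values, with SMAD7 at -0.35 and DLX3 at 0.13 (camera in limma, adjusted p = 0.634).

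Mesenchymal and fibroblast genes were read beside a difference between the controls. Control library 1 alone carried raised levels of fibroblast transcripts. COL1A2 was at 3.94 FPKM there and at 0.257, 0.3001 and 0.208 FPKM in control library 2 and LRG1 libraries 1 and 2, COL3A1 at 3.38 against 0.344, 0.234 and 0.189 FPKM, and VIM at 3.05 against 0.200, 0.257 and 0.146 FPKM. In that library 8 of the 9 listed fibroblast markers were highest, MFAP5 being the exception, and the median ratio to the median of the other libraries was 7.16. Of the 14 markers looked for, DCN, PDGFRA, PDGFRB, FAP and THY1 were not listed for any library. Of 10 genes tested in the list of EMT transcription factors and mesenchymal markers, 8 had a negative log2 fold change (median -0.12, camera in limma, adjusted p = 0.0798), and ELK3, which rose, was the 1 that passed, over all genes and adjusted over the list alone. Without control library 1 the median was -0.11 for this list and -0.06 for the TGF-beta targets (camera in limma, adjusted p = 0.384 and 0.416). This list passed without control library 2 and without a filter (camera in limma, adjusted p = 0.0139 and 0.0427), and its median was -0.07 without LRG1 library 1. COL1A1 belongs to the TGF-beta, EMT and fibroblast lists, and was at 4.76 and 0.939 FPKM in controls and at 1.01 and 0.851 FPKM with LRG1. Of other cell type markers, CD68 was at 2.51 and 3.59 against 3.56 and 2.86 FPKM, CD14 at 0.559 and 0.503 against 0.794 and 0.342 FPKM, and MITF at 3.38 and 2.91 against 3.36 and 3.06 FPKM. The table holds 0 of the 10 endothelial markers and 0 of the 15 long noncoding RNAs looked for, which were not analysed here. For the noncoding RNAs this was fixed in advance, since every gene listed is protein-coding.

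**Figure D3:**
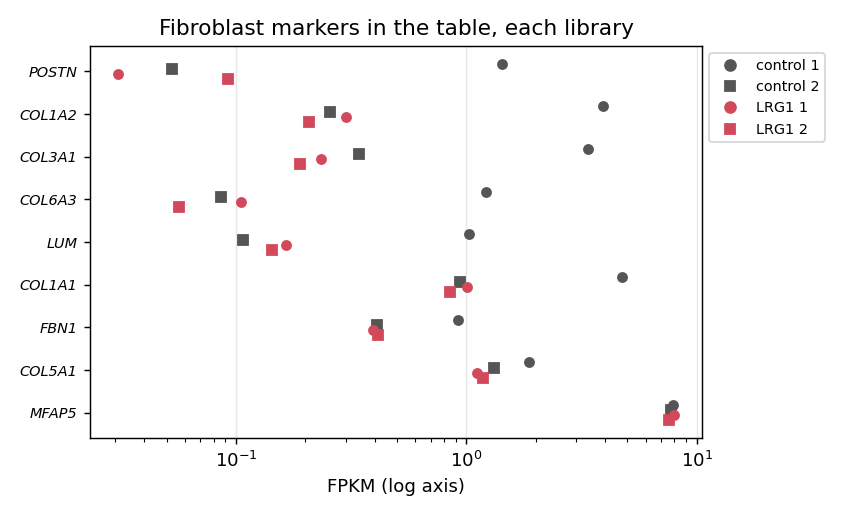
FPKM (log axis) of the 9 fibroblast markers in the table, 1 point per library, with circles for replicate 1, squares for replicate 2, controls in grey and LRG1 in red. Control library 1 is highest in 8 of the 9 genes, by 27.0 times the median of the others for POSTN and 15.3 times for COL1A2.

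Keratinocyte genes did not pass as groups with all 4 libraries. In the epidermal differentiation list 12 of 21 tested genes had a negative value, 0 passed over all genes and 1 adjusted over the list alone. That gene was EVPL (envoplakin, of the cornified envelope), at 11.5 and 9.14 FPKM in controls and 5.23 and 5.00 FPKM with LRG1 (log2 fold change -0.88, limma adjusted p = 0.267 over all genes). KRT1 was at 1.55 and 1.36 against 1.11 and 0.962 FPKM. In the basal keratinocyte and hemidesmosome list 14 of 23 genes were negative (camera in limma, adjusted p = 0.227), with PLEC at a log2 fold change of -0.29. Of 13 activated keratinocyte genes 9 were negative (camera in limma, adjusted p = 0.267), with S100A7 at 2.99 and 1.90 against 0.562 and 0.945 FPKM and S100A9 at a log2 fold change of 0.12. Of 29 genes of matrix proteases and migration 18 were negative (camera in limma, adjusted p = 0.227), with CYR61 at 31.2 and 30.5 against 21.1 and 25.05 FPKM and MMP14 at 67.3 and 67.7 against 77.5 and 74.1 FPKM. Of 22 YAP/TAZ targets, which include CYR61 and NT5E (log2 fold change -0.34), 13 were negative (median -0.08, camera in limma, adjusted p = 0.0755). This list passed without a filter (adjusted p = 0.0399 by camera in limma), without overlapping genes (0.0402) and without LRG1 library 2 (0.00507, median -0.14), but not without LRG1 library 1 (0.527, median -0.05).

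Inflammatory, hypoxia and growth factor lists did not pass with all 4 libraries either. NF-kB genes were negative in 15 of 26 (camera in limma, adjusted p = 0.521), with IL1A at 29.3 and 31.4 against 22.1 and 26.5 FPKM and BIRC3 at 4.68 and 5.07 against 6.33 and 6.24 FPKM. STAT3 targets were negative in 13 of 18 (median -0.03, camera in limma, adjusted p = 0.138), with CEBPD at a log2 fold change of -0.14 and IL4R at -0.56. They passed without control library 2 (median -0.09, adjusted p = 0.0208 by camera in limma), while the median was -0.01 without control library 1 and -0.01 without LRG1 library 1, and -0.05 without LRG1 library 2. Hypoxia targets were negative in 25 of 37 (median -0.04, camera in limma, adjusted p = 0.227), with HK2, hexokinase 2, at -0.23 and ENO1, enolase 1, at -0.11; they passed without LRG1 library 2 (median -0.07, camera in limma, adjusted p = 0.0399), and without LRG1 library 1 the median was 0.01. Angiogenic and growth factors were negative in 9 of 13 (camera in limma, adjusted p = 0.227), with EDN1, endothelin 1, at -0.30 and NRP1 at -0.18. Notch targets were positive in 7 of 11 (median 0.10, camera in limma, adjusted p = 0.227), with NOTCH1 at 0.14 and NOTCH3 at 0.19; the median was 0.05 without LRG1 library 1 and 0.02 under the stricter filter. Wnt targets had a median of -0.09 but a mean of 0.12 over 7 genes, with DKK1 at -0.22 and SP5 at -0.14, and camera in limma gave a downward direction (adjusted p = 0.227). That median was -0.02 without LRG1 library 1 and -0.03 without control library 2. MYC, a member of the Wnt and immediate early lists, was at 3.23, 3.18 and 3.16 FPKM in 3 libraries and at 28.6 FPKM in LRG1 library 1.

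Lists of proliferation genes had small medians. GINS4, given above among the genes that fell, is in neither the S phase nor the G2/M list. S phase genes were positive in 20 of 35 (median 0.01, camera in limma, adjusted p = 0.925), with RFC2 at 0.11 and FEN1 at -0.10. Their median was -0.03 without control library 1, 0.03 without control library 2 and 0.00096 without LRG1 library 1. G2/M genes were positive in 27 of 38 (median 0.03, adjusted p = 0.227 by camera in limma), with CDC25C at 0.23 and ANLN at 0.10. The G2/M list passed without LRG1 library 2 (median 0.04, camera in limma, adjusted p = 0.0399), and its median was 0.04 without control library 1, 0.01 without control library 2 and 0.000572 without LRG1 library 1. Cytosolic ribosomal protein genes were positive in 54 of 73 (median 0.02, camera in limma, adjusted p = 0.0618), with RPL29 at 0.34, but with its estimated correlation of 0.298 camera in limma gave p = 0.527 and adjusted p = 0.777. At the preset correlation this list passed under quantile normalisation (adjusted p = 0.0168 by camera in limma), a common total (0.0231), no filter (0.0420), the stricter filter (0.0430), the replicate block (0.0371) and without overlapping genes (0.0137). It also passed without LRG1 library 2 (median 0.05, adjusted p = 0.000818 by camera in limma) and without control library 1 (median 0.06, adjusted p = 0.00310), but not without LRG1 library 1 (median 0.00258, 0.855) or control library 2 (median 0.00634, 0.767). Oxidative phosphorylation genes were positive in 26 of 38 (adjusted p = 0.227 by camera in limma), with COX7A2 at 0.09. Of 13 mitochondrially encoded genes 7 were negative (adjusted p = 0.653 by camera in limma), with MT-CO3 at -0.10 and MT-ATP8 at -0.16, and of 16 replication-dependent histone genes 10 were negative (adjusted p = 0.521 by camera in limma), with HIST1H1C at -0.38 and HIST1H2AM at 0.87.

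Lipid and stress lists gave 2 genes adjusted over the list alone. Both were in the list of ER chaperones and the unfolded protein response (12 of 20 positive, camera in limma, adjusted p = 0.267), which had 0 over all genes tested. CANX, the ER chaperone calnexin, was at 51.2 and 58.1 FPKM in controls and 105 and 101 FPKM with LRG1 (log2 fold change 0.91, limma adjusted p = 0.0748 over all genes), and XBP1, a transcription factor of the unfolded protein response, was at 14.7 and 14.9 against 8.92 and 7.50 FPKM (log2 fold change -0.78, limma adjusted p = 0.202). Cholesterol biosynthesis genes were positive in 17 of 25 (median 0.07, camera in limma, adjusted p = 0.198), with INSIG1, which retains the SREBP complex in the ER, at -0.48; the median was 0.03 without LRG1 library 1. Lipogenesis genes were positive in 7 of 12 (adjusted p = 0.227 by camera in limma), with SCD at 0.15 and ME1 at 0.14. NRF2 targets were positive in 13 of 24 (adjusted p = 0.277 by camera in limma), with AKR1B10 at 0.21 and TXNRD1 at 24.6 and 38.8 against 48.9 and 46.8 FPKM. Integrated stress response genes had a median of -0.01 although camera in limma gave an upward direction (adjusted p = 0.784), with PSPH at -0.34 and SLC7A5 at 0.10. The p53 targets had a median of 0.02 with a downward direction by camera in limma (adjusted p = 0.925), with TNFRSF10B at -0.14 and FDXR at -0.17. Heat shock genes had a median of 0.01 and a mean near 0 (-0.00192), with an upward direction by camera in limma (adjusted p = 0.925), STIP1 at 0.11 and DNAJA1 at -0.14. With each library left out in turn, these medians ran from -0.02 to 0.02 for the integrated stress response, from -0.03 to 0.01 for p53 targets and from -0.02 to 0.04 for heat shock genes. Apart from EVPL, ELK3, CANX and XBP1, 0 members of any list passed when adjusted over the list alone.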

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

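The alternatives were planned, except the test without overlapping genes, which was chosen after the data were seen. The counts of 12 higher, 12 lower, 21 at 2-fold and 2 lists stayed within 1.5 times under the other pseudocount, the stricter filter and each rescaling, and the counts of genes also without a filter, which gave 7 lists. Moderation without the trend called 3 higher, 7 lower and 10 at 2-fold. Without overlapping genes 5 were higher, 7 lower and 10 at 2-fold, with 4 lists, in part because 10 called genes were removed. Leaving out 1 library gave 0 to 1 higher, 0 to 1 lower, 0 to 1 at 2-fold and 0 to 7 lists, with fewer libraries to estimate the spread and the lone library assumed to vary like the others. Camera with an estimated correlation called 0 lists and fry 0. With each of these tests the interferon and immediate early lists were lost, and these losses are not among the pairs counted below. The 24 called genes kept their sign in every alternative that tested them, which their close replicates largely fixed in advance. No result changed direction past the threshold. Causes of the other changes were not tested. Adjusted p values ranged from 0.000182 to 0.699 for the immediate early list, which was lost under the stricter filter (0.109) while the ribosomal list passed, and from 0.000818 to 0.699 for the interferon list (limma camera). Over all pairs of a named gene and an alternative, 133 lost the threshold and 2 gained it, and over pairs of a list and an alternative 3 lost and 19 gained it.

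The replicate number used as a replicate block called 0 genes higher, 0 lower and 0 at 2-fold in limma, with 475 at an unadjusted p under 0.05, and 3 lists. The block leaves fewer residual degrees of freedom than the main model, so its 0 gene calls cannot be read as an effect of pairing. The differences between libraries 1 and 2 were uncorrelated between the groups across genes (r = -0.0121). The labels do not say that a number marks a shared day. However, comparing libraries numbered 2 with those numbered 1 called the ribosomal protein list (limma camera, adjusted p = 2.72e-05), the NF-kB list and 1 gene. The other comparison that crosses the treatment called 0 lists and 0 genes. A factor shared by number is thus left open for some genes, and the numbers were not taken to pair the libraries. Planned tests for count data were not run because the table holds FPKM. Depth is unknown, so what it limits cannot be stated.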

Other observations

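The tests of the splits, the level switches, the overlap, the partners of genes that fell, the fibroblast transcripts and the left-out library were chosen only after the result was seen; those of the signs of all partners and of the lists in other splits were set beforehand.

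Several abundant genes sat at 2 distinct levels that did not follow LRG1. CLDN4, a tight junction claudin, was at 19.1 FPKM in control library 2 and 20.02 FPKM in LRG1 library 1 and at 0.0418 and 0.369 FPKM in the other libraries. BCL2L2, an anti-apoptotic BCL2 relative, was at 1.93 and 1.91 FPKM in control library 1 and LRG1 library 1 and at 18.9 and 20.2 FPKM in control library 2 and LRG1 library 2. IGFBP3, an IGF-binding protein, was at 102 and 107 FPKM in control library 1 and LRG1 library 2 and at 45.0 and 48.5 FPKM in the others. Genes with 1 library over 1 log2 unit from 3 closely matched ones numbered 20 and 22 for control libraries 1 and 2 and 24 and 24 for the LRG1 libraries, and in 68 of these 90 the lone library was lower.

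The 24 genes past the threshold may in part be such level switches that fell along the groups. Genes at 2 tight levels over 1 log2 unit apart numbered 21 in the real split, 18 of them among the called genes, against 12 and 10 in the splits that cross the treatment (exact binomial p = 0.0356 against equal shares), and at a gap of 0.5 they numbered 57, 45 and 51 (exact binomial p = 0.304). Both tests take the genes as independent although all come from the same libraries, so their p-values do not measure variation between libraries. Overlap of the gene span with another protein-coding gene on the same strand held for 41.7% of called genes and 11.7% of the others (Fisher's exact p = 0.000209). Such spans include introns, so overlap need not mean shared reads. But 4 of 11 tested partners had the opposite sign (exact binomial p = 0.549). Among the 4 were TRIM16, at 22.2 FPKM in controls and 5.16 FPKM with LRG1, beside AC005324.3, and MUC1 and C17orf49, at log2 fold changes of -0.01 and -0.06. Of the 3 splits, 1 gave as many called genes, the real one with 24 against 1 at most in the others; 3 splits are too few for a share under 0.05. Loss of reads to the tested partners of the genes that fell is argued against, since SNRNP27, FAM193A, HOOK2 and GNB1L, beside MXD1, RNF4, PRDX2 and RTL10, had a median log2 fold change of -0.0262 (-0.06 to -0.01); it stays open for the other overlaps, while 14 called genes overlap no such gene in the annotation used, and for all 24 a response to LRG1 and switches of level cannot be told apart with 2 libraries per group.

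Fibroblast transcripts in control library 1 are consistent with RNA from another, fibroblast-like source in that library. Highest there were 8 of the 9 fixed markers listed, and COL1A1, COL1A2, SPARC and VIM reached 4.76, 3.94, 4.89 and 3.05 FPKM, while KRT14 stayed at 613 FPKM against 598 FPKM in control library 2. The list had 14 markers, and COL1A1 and COL3A1 are also in the EMT list. The markers DCN, PDGFRA, PDGFRB, FAP and THY1 were not listed for any library, so no rise in control library 1 is seen for them. A TGF-beta response of the keratinocytes as the whole source is argued against by their TGF-beta targets, whose median log2 difference, control library 1 minus 2, was 0.0310 (quartiles -0.05 and 0.07, 20 genes), although TGFBI differed by 0.30 and CTGF, too low to be among the 20, was at 2.72 FPKM there and 0.861, 0.595 and 0.701 FPKM in the others. The path by which such RNA entered, in culture or later, was not tested.

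The lower immediate early list may rest in good part on LRG1 library 1, while for the interferon list this stays open. Of the 4 libraries left out in turn, that one alone ended both calls (limma camera, adjusted p = 0.527), but the immediate early median went from -0.07 to -0.0291 and the interferon median from -0.13 to -0.0909, near the -0.11 to -0.12 with any other library left out. Of the splits that cross the treatment, 0 called the interferon list (limma camera, adjusted p = 0.225 and 0.693) and 0 the immediate early list (0.143 and 0.102), which had been set beforehand as evidence against variation unrelated to LRG1. That bound was too lenient, since the split of libraries numbered 2 against 1 called the ribosomal protein list (limma camera, adjusted p = 2.72e-05) and the NF-kB list, whose estimated correlations were 0.298 and 0.177, against 0.175 for the immediate early list. The estimates are made from the same differences within the groups that the crossing splits compare, so they are not separate evidence. For the interferon list the estimate was 0.00933, which goes against correlation. But with 2 residual degrees of freedom its 95% interval ran from -0.03 to the limit of 1. So for both lists a small effect of LRG1 and variation of correlated genes between libraries cannot be told apart with these 4 libraries.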
